A study of Aquarana catesbeiana with 18 samples.

How the data were processed

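RNA sequencing libraries of skin, liver and eyes from albino and wild-type American bullfrogs were compared, 3 libraries in each of 6 groups. The deposited counts are whole reads per gene as the authors made them, with no normalization. The deposited FPKM values are per kilobase and per 1e6 counted reads of the same library, computed by the authors from those counts, with 1 gene length for all libraries. The submitters' processing notes name HISAT2 and HTSeq, without versions. The genome build, the strandedness and the handling of reads that match several genes are not given in the sources used here. All 24636 gene identifiers occur in the RefSeq table of assembly ASM4218655v1, which was used for names and for the order of neighbouring genes only. Of the genes, 22100 are protein coding and 2536 non-coding, and 11611 are named by a locus number. Total counts per library lay between 34.3 and 39.2 M.

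The tests, the gene lists, the naming rule and the first set of alternatives were fixed before the data were examined. Counts were analysed in R 4.3.3 with edgeR 4.0.16: genes were kept by filterByExpr within each comparison, libraries were scaled by TMM, and albino was compared with wild-type in each tissue by the robust quasi-likelihood test (glmQLFit and glmQLFTest) with Benjamini-Hochberg (BH) adjustment at a false discovery rate of 0.05. The SE of a log2 difference was taken as its size divided by the square root of F. The difference of the genotype effect between tissues was tested as an interaction for each pair of tissues. Genes called in the same direction in all 3 tissues were counted. A group with 0 counts was set to a floor of 3 counts over the group, and a group with 1 to 3 counts is given as a ratio with its 95% counting interval. CPM of single genes are over the library total scaled by TMM within each tissue. Shares of counts, sums and percentages of lens and phototransduction genes, the covariate and the on and off states are over unscaled library totals.

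Lists of genes were tested with camera from limma 3.58.1 (preset correlation 0.01, two-sided, at least 5 tested genes), with the estimated correlation and fry as alternatives. The 26 lists were melanin synthesis and melanosome, melanocyte regulators, iridophore and xanthophore pigment, antioxidant defence, glutathione transferase and xenobiotic, reactive oxygen producing oxidases, DNA damage and p53 response, heat shock and unfolded protein response, oxidative phosphorylation, ribosomal proteins, inflammation and acute phase, complement, interferon response, lipid and bile acid metabolism, glucose and amino acid metabolism, phototransduction, retinal pigment epithelium and visual cycle, lens crystallins, epidermis and keratin, extracellular matrix and cell cycle, and markers of skeletal muscle, erythrocytes, macrophages and granulocytes, lymphocytes and hepatocytes. Symbols were matched exactly, and products described as like another gene were left out of the lists.

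Genes were named by rule. In each tissue these were the 6 largest rises and the 6 largest falls among called genes with a log2 difference of at least 1, a mean of at least 1 CPM in the higher group, groups that do not overlap and a symbol, then TYR, TYRP1, DCT, PMEL, MLANA, OCA2, SLC45A2, MITF, SOX10, MC1R, SOD1, SOD2, CAT, GPX1, NFE2L2 and HMOX1 whether called or not. Up to 3 members with the smallest p were named from each list that passed, and the 3 smallest p from each interaction test. Genes called in all tissues were named where they have a symbol. Some genes picked by this rule are counted but not reported here.

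The code was tested on simulated data made with known changes. At a log2 change of 1 and 2 it recovered 0% and 39.2% of changed genes in skin, 9.28% and 79.2% in liver, and 29.3% and 78.6% in eyes. False calls were 15.6%, 12.4% and 6.20% of all calls in skin, liver and eyes, above the 5% aimed at. The interaction tests recovered 3% and 16% between skin and liver, 0% and 17% between skin and eyes, and 5% and 46% between eyes and liver. A list shifted by 0.5, oxidative phosphorylation, was found in each tissue, and 1 other list was called in eyes. The simulated genes varied independently of each other, while in the data this list had an estimated correlation of 0.701, 0.331 and 0.228 in skin, liver and eyes. The simulation therefore does not show how often camera with the preset correlation calls lists falsely here.

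Whether equal replicate numbers mark related libraries was checked by correlating residuals across genes within groups, which are not independent replicates. Albino and wild-type libraries of the same number had r from -0.182 to 0.0715 and were treated as unpaired. Skin and eyes of the same number and genotype had r from 0.210 to 0.546, while wild-type 3 of liver had 0.0659 with skin and 0.0952 with eyes.

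The alternatives were DESeq2 1.42.0, RLE scaling, no count filter, a replicate block, 1 fit of all 18 libraries, limma on log2 FPKM with 1 or 0.1 added, a minimum log2 difference of 1, and each library left out in turn. Added after the data were seen were scaling by library totals, lists with products described as like a member, eyes without albino libraries 1 and 2, beta crystallin level as a covariate in eyes, and liver wild-type 2 and 3 summed as 1. Other splits of the libraries were refitted in the same way. Genes on in some animals and off in others were defined in each tissue by a gap of more than 3 in log2 of CPM with 0.05 added. Pathways of the deposited annotation with at least 10 genes were tested for enrichment among called genes by Fisher's exact test, one-sided, against tested genes with a pathway.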

Results

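RNA sequencing was run on skin, liver and eyes of albino and wild-type American bullfrogs. The 18 libraries form 6 groups, 1 for each genotype in each tissue, with 3 libraries per group. Total counts ran from 35.7 to 36.8 M per library in skin, from 38.3 to 39.2 M in liver and from 34.3 to 36.4 M in eyes. The count table holds 24636 genes, of which between 19584 and 20784 had a count in a skin library, 18080 to 18561 in a liver library and 20583 to 20859 in an eye library. The labels do not say whether replicates are separate animals. The genome build of the authors is not given in the sources used here, so no coordinates are reported. Oxidative stress and UVB measurements were not analysed here. Values below are counts per 1e6 counts (CPM) with SD and log2 differences of albino minus wild-type with SE, each with n = 3 libraries per group. Adjusted p-values for genes come from edgeR's quasi-likelihood test with BH adjustment. Intervals and floors cover counting error only.

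Whether genes of the pigment pathway differ in the skin of an animal without melanin is the question of the skin comparison. Tyrosinase (TYR), the enzyme that starts melanin synthesis, rose from 8.83 ± 2.03 CPM in wild-type skin to 61.6 ± 12.8 CPM in albino skin, a log2 difference of 2.80 ± 0.27 (adjusted p = 0.0163). MYRFL, a gene related to the myelin regulatory factor, had 1 count over the wild-type libraries against 13.1 ± 0.186 CPM in albino skin, a ratio of 1446 with a 95% counting interval of 259 to 57143. The coiled-coil gene CCDC148 rose by 3.61 ± 0.41. Genes for proteins like the zymogen granule protein ZG16 also rose, by 6.61 ± 0.80 for LOC141147568, 6.48 ± 0.63 for LOC141148439 and 6.13 ± 0.66 for LOC141148436, and how reads were shared between such similar copies is not given. Among the genes that fell, IGFBP1, which binds insulin-like growth factors, dropped from 34.3 ± 0.189 to 8.32 ± 1.20 CPM, a log2 difference of -2.05 ± 0.20. The NXPE3-like gene LOC141133579 differed by -2.62 ± 0.23. The Fc receptor-like gene FCRL5 (LOC141116641) had 2.39 ± 0.291 CPM in wild-type skin and 1 count over the albino libraries, a ratio of 261 with an interval of 46.5 to 10353. In all, 16 of 16921 tested genes passed, 10 higher and 6 lower in albino skin, and 12 of the 16 carry only a locus number. Groups did not overlap for 19.8% of the tested genes, where chance gives 10% averaged over all splits of the libraries. Genes vary together, so a single split can lie well away from that average, and the share was not computed for other splits. None of the 10 calls picked by the naming rule held without each library: of the 10, 2 were lost without wild-type 1 (adjusted p 0.0552), 3 without wild-type 2 (up to 0.0743), 2 without wild-type 3 (up to 0.0672), 9 without albino 1 (up to 0.119), 10 without albino 2 (up to 0.170) and 10 without albino 3 (up to 0.153). The count of called genes was 51, 26 and 33 without wild-type 1, 2 and 3, then 3, 0 and 0 without albino 1, 2 and 3. These counts of 0 are edgeR's, beside 1531 and 1598 genes at an unadjusted p under 0.05, and DESeq2 called 757 genes with all libraries. The balance of directions was not stable. Without wild-type 1, 18 genes were higher and 33 lower, and DESeq2 gave 346 and 411, while without wild-type 2 it was 19 and 7.

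The melanin and melanosome list had 28 tested members in skin, of which 1 passed over all genes and 10 were higher and 1 lower when adjusted over the list alone. Its members included PMEL, the fibril protein of melanosomes, at 127 ± 39.0 CPM in wild-type and 749 ± 99.8 CPM in albino skin (log2 difference 2.57 ± 0.33, adjusted p = 0.0569). TYRP1, a later enzyme of the pathway, differed by 1.71 ± 0.26 (adjusted p = 0.0880), the melanosome transporter OCA2 by 3.10 ± 0.53 (0.0992), MLANA by 1.28 ± 0.22 (0.102) and the transporter SLC45A2 by 1.02 ± 0.21 (0.133), and none of these 5 passed. DCT, which acts between tyrosinase and TYRP1, stood at -0.97 ± 0.40 (adjusted p = 0.375) and did not pass either. The list as a whole was higher than other genes in the camera test (median log2 difference 0.34, mean 0.67, adjusted p = 2.67e-07), with adjusted p = 0.160 with an estimated correlation. Its per-library medians were 0.40, 0.44 and 0.59 in albino and -0.05, 0.16 and 0.07 in wild-type skin. The regulators of pigment cells did not pass: MITF stood at 0.20 ± 0.35, SOX10 at 0.49 ± 0.28 and the melanocortin receptor MC1R at -0.98 ± 0.59. The genes of the antioxidant rule did not pass either, with SOD1 at 0.29 ± 0.31, SOD2 at 0.08 ± 0.26, catalase (CAT) at 0.36 ± 0.27, GPX1 at 0.11 ± 0.34, NFE2L2 at -0.02 ± 0.26 and HMOX1 at -0.25 ± 0.36. TYR in skin lost its call without wild-type 2 (adjusted p = 0.0516), albino 1 (0.0974), albino 2 (0.0783) or albino 3 (0.102). The antioxidant list of 42 tested genes had an adjusted p of 0.883 and the list of 15 melanocyte regulators one of 0.583, each with 0 called members.

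**Figure D1:**
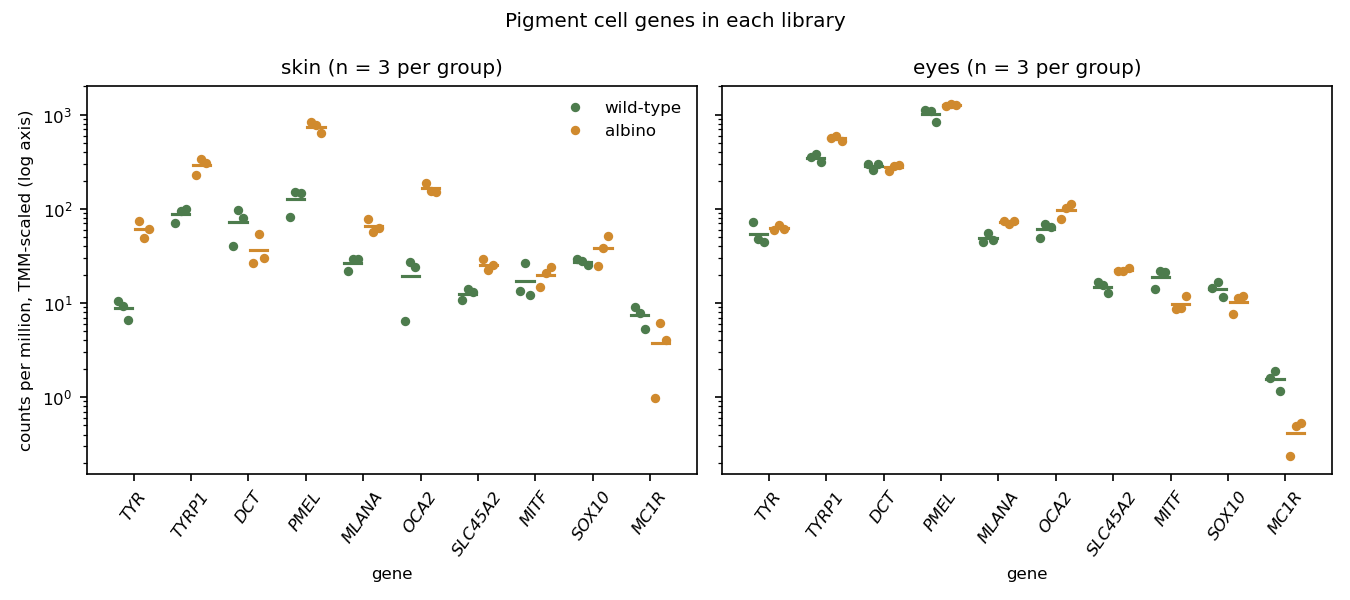
CPM on a log axis of the melanosome genes and pigment cell regulators of the naming rule in skin and eyes, 1 point per library, with group means. In skin, TYR runs from a wild-type mean of 8.83 to an albino mean of 61.6 CPM, while in eyes the means are 54.6 and 62.8 CPM.

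Some marker lists of other cell types passed camera in skin. Skeletal muscle markers were higher in albino skin (adjusted p = 8.29e-06; 0.714 with an estimated correlation), with per-library medians of 1.10, 4.08 and 1.39 in albino and -0.07, -0.02 and 0.30 in wild-type skin, and 5 of 10 tested members were higher when adjusted over the list alone with 0 over all genes. PYGM, the glycogen phosphorylase of muscle, had 0 counts in wild-type skin and 12.5 ± 10.2 CPM in albino skin, at least 445-fold more against a floor of 3 counts over the group, and did not pass (adjusted p = 0.161). Slow troponin C (TNNC1, LOC141102624) stood at 0.926 ± 0.131 and 4.28 ± 1.59 CPM, and MYBPC1, a protein of the thick filament, at 0.140 ± 0.138 and 3.55 ± 4.00 CPM. Lymphocyte markers were lower as a list (17 tested, median -0.98, adjusted p = 0.00124; adjusted p = 0.824 with an estimated correlation), with the T cell genes CD8A at -1.29 ± 0.45 and CD8B at -1.62 ± 0.65. Macrophage and granulocyte markers were lower as a list (17 tested, median -0.70, adjusted p = 0.0240; 0.944 with an estimated correlation), though per-library medians overlapped (1.12, -0.58 and -0.52 in wild-type, -0.12, -0.18 and -1.36 in albino skin), with lysozyme (LYZ) at -1.32 ± 0.44, CTSS at -1.37 ± 0.54 and MSR1 at -2.37 ± 1.03. Cell cycle genes were lower as a list (34 tested, median -0.32, adjusted p = 0.0153; 0.944 with an estimated correlation), though albino 3 had the highest median (0.35, -0.33 and -0.03 in wild-type, -0.54, -0.82 and 0.41 in albino skin), among them RRM2 and RRM1, subunits of the enzyme that makes deoxyribonucleotides, at -0.96 ± 0.25 and -0.92 ± 0.33, and NUSAP1 at -1.07 ± 0.37. These 3 lists had 0 members past the threshold over all genes or over the list alone. Without wild-type 1, the lymphocyte (adjusted p = 0.1003), macrophage (0.984) and cell cycle (0.411) lists lost their calls. The cell cycle list also lost its call without albino 1 (0.138) or albino 2 (0.465), and the macrophage list without albino 3 (0.303).

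Of 26 lists tested in skin, 5 passed and 21 did not. Every other split of the skin libraries called at least 5 lists (highest 11), so this number is no larger than arbitrary groupings gave. With an estimated correlation camera called 0 lists, with 1 at an unadjusted p under 0.05, and fry, which asks whether a list's genes move 1 way on balance, called 1, the melanin list (adjusted p = 0.0142). The erythrocyte markers (adjusted p = 0.0534), lipid and bile acid genes (0.0967) and interferon genes (0.166) were nearest to passing. The inflammation list had an adjusted p of 0.282, the DNA damage and hepatocyte lists 0.351, and the iridophore and xanthophore, glutathione transferase and glucose lists 0.484. The oxidases and visual cycle lists had 0.526, the ribosomal protein and extracellular matrix lists 0.541, the heat shock list 0.667, oxidative phosphorylation 0.703, complement and phototransduction 0.837, keratin 0.866 and the lens list 0.912. The median, the mean and the test differ in sign for complement, phototransduction, visual cycle and lens genes. The count of lists was 2 without wild-type 1 and 9 without wild-type 3. With products like a member added to the lists 8 passed, and the macrophage list did not (0.199). The glutathione transferase (adjusted p = 0.00934), lipid (0.0236), erythrocyte (0.0236) and interferon (0.0426) lists passed camera only with these products. The glutathione transferase list then had 30 tested genes, where it had 8 without them.

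Liver stores, detoxifies and secretes for the whole body, and the liver comparison asks whether an organ away from the pigmented surface differs as well. A gene for a D-dopachrome decarboxylase-like protein (LOC141128626), whose relatives act on a compound of the dopachrome family, rose from 0.564 ± 0.0413 to 125 ± 20.6 CPM, a log2 difference of 7.79 ± 0.25 (adjusted p = 2.35e-06). The intelectin-like gene LOC141147786, of a family of sugar-binding proteins, had 0 counts in wild-type liver and 9.36 ± 1.35 CPM in albino liver, at least 394-fold more against a floor of 3 counts over the group. MYRFL had 1 wild-type count against 11.2 ± 0.566 CPM (ratio 1431, interval 256 to 56569), and the keratin 19-like gene LOC141114312 had 1 against 3.71 ± 0.483 CPM (ratio 473, interval 84.3 to 18713). The axonemal dynein DNAH10 had 1 against 26.6 ± 26.1 CPM (ratio 3154, interval 566 to 124630), and ST8SIA1, a sialyltransferase of gangliosides, rose by 5.94 ± 0.66. Among the genes that fell, the SCO-spondin-like gene LOC141110349 went from 88.8 ± 20.9 CPM to 0, at least 3122-fold lower. The sulfotransferase 2B1-like gene LOC141110921 was at least 188-fold lower and the flavin monooxygenase 5-like gene LOC141103358 at least 84.8-fold lower. The muscle actinin ACTN3 had 15.8 ± 0.561 CPM against 3 albino counts (ratio 558, interval 191 to 2708). The CEACAM1-like gene LOC141110635 had 18.2 ± 8.74 CPM against 1 count (ratio 1923, interval 345 to 75972) and TPD52L1 3.19 ± 0.0427 CPM against 1 (ratio 338, interval 60.4 to 13401). Heme oxygenase 1 (HMOX1), which breaks down heme, fell from 197 ± 6.33 to 90.8 ± 20.4 CPM, a log2 difference of -1.12 ± 0.21 (adjusted p = 0.0223).

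In liver 864 of 14990 tested genes passed, 429 higher and 435 lower in albino animals. Groups did not overlap for 28.7% of tested genes, where chance gives 10% averaged over all splits, from which a single split can differ. Scaled by library totals, 1182 genes passed and 20.6% of them were higher, since that scaling moves the median log2 difference of all genes to -0.28, and every direction given here is relative to the median of all genes. GPX1 stood at 0.83 ± 0.34 (adjusted p = 0.190), NFE2L2 at 0.46 ± 0.20, SOD1 at 0.28 ± 0.19, CAT at 0.05 ± 0.21, SOD2 at -0.14 ± 0.27 and MITF at 0.27 ± 0.21, and none of these 6 passed. SOD1, CAT and MITF turn negative under library totals, at -0.02, -0.24 and -0.0042. TYR, TYRP1, DCT, PMEL, MLANA, OCA2, SLC45A2, SOX10 and MC1R lay below the count filter in liver. Wild-type libraries 2 and 3 had the same state at 100% of 70 genes that were on in some animals and off in others, and liver p-values treat these libraries as separate animals. With both summed as 1 library, 147 genes passed, and 15 of 27 calls picked by the naming rule were lost, among them HMOX1 in liver (adjusted p = 0.0908) and DNAH10 in liver (0.168). The count was 1381 without wild-type 1, 134 without wild-type 2, 183 without wild-type 3, 257 without albino 2 and 306 without albino 3. Of 27 calls picked by the naming rule, 12 held without each library, among them LOC141128626, LOC141147786, LOC141110349, ACTN3 and MYRFL. The others were lost in part, 4 without wild-type 1 (adjusted p up to 0.125), 14 without wild-type 2 (up to 0.274, DNAH10), 14 without wild-type 3 (up to 0.184), 12 without albino 2 (up to 0.152) and 10 without albino 3 (up to 0.148). HMOX1 was lost without wild-type 2 (0.110), wild-type 3 (0.0875), albino 2 (0.0819) or albino 3 (0.0767).

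Extracellular matrix genes lay higher as a list in albino liver: 7 of 34 tested members passed over all genes and 14 were higher when adjusted over the list alone (median 0.76, adjusted p = 1.77e-06; adjusted p = 0.616 with an estimated correlation). Albino 1 stood within the wild-type range (per-library medians -0.10, 0.17 and -0.03 in wild-type, 0.14, 0.96 and 0.95 in albino liver). SERPINH1, the collagen chaperone, rose by 1.81 ± 0.29, the microfibril protein FBN1 by 1.08 ± 0.18 and the collagen crosslinker LOX by 1.93 ± 0.36. Erythrocyte markers lay higher (11 tested, 3 called, 8 over the list alone, median 0.85, adjusted p = 0.000394; 0.616 with an estimated correlation), with the anion exchanger SLC4A1 at 1.49 ± 0.27, the heme synthesis enzyme ALAS2 at 1.64 ± 0.33 and spectrin beta (SPTB) at 0.88 ± 0.20. Hepatocyte markers lay higher (18 tested, 4 called, median 0.51, adjusted p = 0.00533; 0.616 with an estimated correlation), with 6 higher and 1 lower when adjusted over the list alone. Fibrinogen gamma (FGG) went from 5827 ± 1625 to 16323 ± 3328 CPM, and the FABP1 copies LOC141129948 and LOC141128285, which carry fatty acids, rose by 2.71 ± 0.39 and 2.88 ± 0.50. Ribosomal protein genes lay higher (76 of 76 positive, 0 called over all genes or over the list alone, median 0.34, adjusted p = 0.000319; 0.706 with an estimated correlation), with RPL21 (LOC141112834) at 0.72 ± 0.18, RPS21 at 0.68 ± 0.20 and RPS12 at 0.64 ± 0.24. Oxidative phosphorylation genes had a median of 0.25 (48 tested, 0 called, adjusted p = 0.0248; 0.675 with an estimated correlation), which turns to -0.03 under library totals. Among them SDHD stood at 0.67 ± 0.17, COX6C at 0.67 ± 0.18 and ATP5F1D at 0.61 ± 0.19, and none of these passed. Without wild-type 2 or 3 or albino 2, the calls of SERPINH1 (adjusted p up to 0.0807), FBN1 (up to 0.0874), LOX (up to 0.0807), ALAS2 (up to 0.147), SPTB (up to 0.171) and FGG (up to 0.128) were lost. FBN1, LOX, SPTB and FGG were also lost without albino 3, and ALAS2 and SPTB without wild-type 1. SLC4A1 was lost without wild-type 2 or 3 or albino 3 (up to 0.110), LOC141129948 without wild-type 3 (0.0588) and LOC141128285 without wild-type 2 or 3 or albino 2 (up to 0.109). With wild-type 2 and 3 summed all 9 of these genes lost their calls (adjusted p up to 0.125, SPTB in liver), and the lists still passed.

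As a list, the oxidases that make reactive oxygen lay lower in albino liver, with 9 of 9 tested members negative (1 called, 2 over the list alone, median -0.65, adjusted p = 0.00474; adjusted p = 0.616 with an estimated correlation). CYBA, a subunit of the phagocyte NADPH oxidase, fell from 24.5 ± 3.25 to 13.0 ± 2.24 CPM, while its partner CYBB stood at -0.75 ± 0.27 (adjusted p = 0.146) and NOS2 at -2.33 ± 0.58 (0.0530). Macrophage and granulocyte markers lay lower as a list (17 of 17 negative, 2 called, 3 over the list alone, median -0.50, adjusted p = 0.00474; 0.675 with an estimated correlation), though albino 1 lay above wild-type 2 and 3 (per-library medians 0.48, -0.21 and -0.29 in wild-type, -0.04, -0.68 and -0.76 in albino liver). LYZ fell by 1.44 on the log2 scale (SE 0.22) and cathepsin S (CTSS) by 1.29 (SE 0.30), and the MARCO row LOC141147286 stood at -2.03 ± 0.53. Lymphocyte markers lay lower as a list (19 tested, 15 negative, 1 called, 1 over the list alone, median -0.58, adjusted p = 0.00777; 0.616 with an estimated correlation). Its called member XBP1, which drives secretion in plasma cells and is expressed in hepatocytes too, fell from 414 ± 101 to 172 ± 36.2 CPM, and LCK stood at -0.99 ± 0.28 and CD8B at -1.45 ± 0.45. Without wild-type 1 the oxidases (adjusted p = 0.0529), macrophage (0.136) and oxidative phosphorylation (0.182) lists lost their calls. The last was also lost without albino 1 (0.210), and the hepatocyte list was lost without wild-type 3 (0.164) or albino 2 (0.0657). CYBA was lost without wild-type 2 or 3 or albino 2 or 3 (up to 0.1003), as were XBP1 (up to 0.131) and CTSS (up to 0.152), the last also without wild-type 1, and LYZ was lost without wild-type 2 (0.0734). With wild-type 2 and 3 summed CYBA, LYZ, CTSS and XBP1 lost their calls (adjusted p up to 0.112, XBP1 in liver), and the 3 lists still passed.

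Of 24 lists tested in liver, 8 passed, and the 4 tested skeletal muscle genes were under the minimum for a test. With an estimated correlation camera called 0 lists, with 0 at an unadjusted p under 0.05, and fry called 1, the visual cycle list (adjusted p = 0.00133). In camera that list had an adjusted p of 0.0557, as had complement, and the lipid list had 0.0534. The interferon list had 0.153, DNA damage 0.277, phototransduction 0.337, antioxidant defence 0.348, glutathione transferases 0.365, inflammation 0.405, keratin 0.572, glucose and amino acids 0.635, heat shock 0.710, iridophore and xanthophore 0.838, melanocyte regulators and cell cycle 0.871, and melanin 0.930. In antioxidant defence 3 of 39 tested genes rose and 3 fell. With products like a member 11 lists passed, and inflammation turned from lower to higher (0.0267). The complement (0.00144) and visual cycle (0.0188) lists also passed camera only then. The median, the mean and the test differ in sign for the DNA damage, glucose, phototransduction, melanocyte regulator and cell cycle lists.

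**Figure D2:**
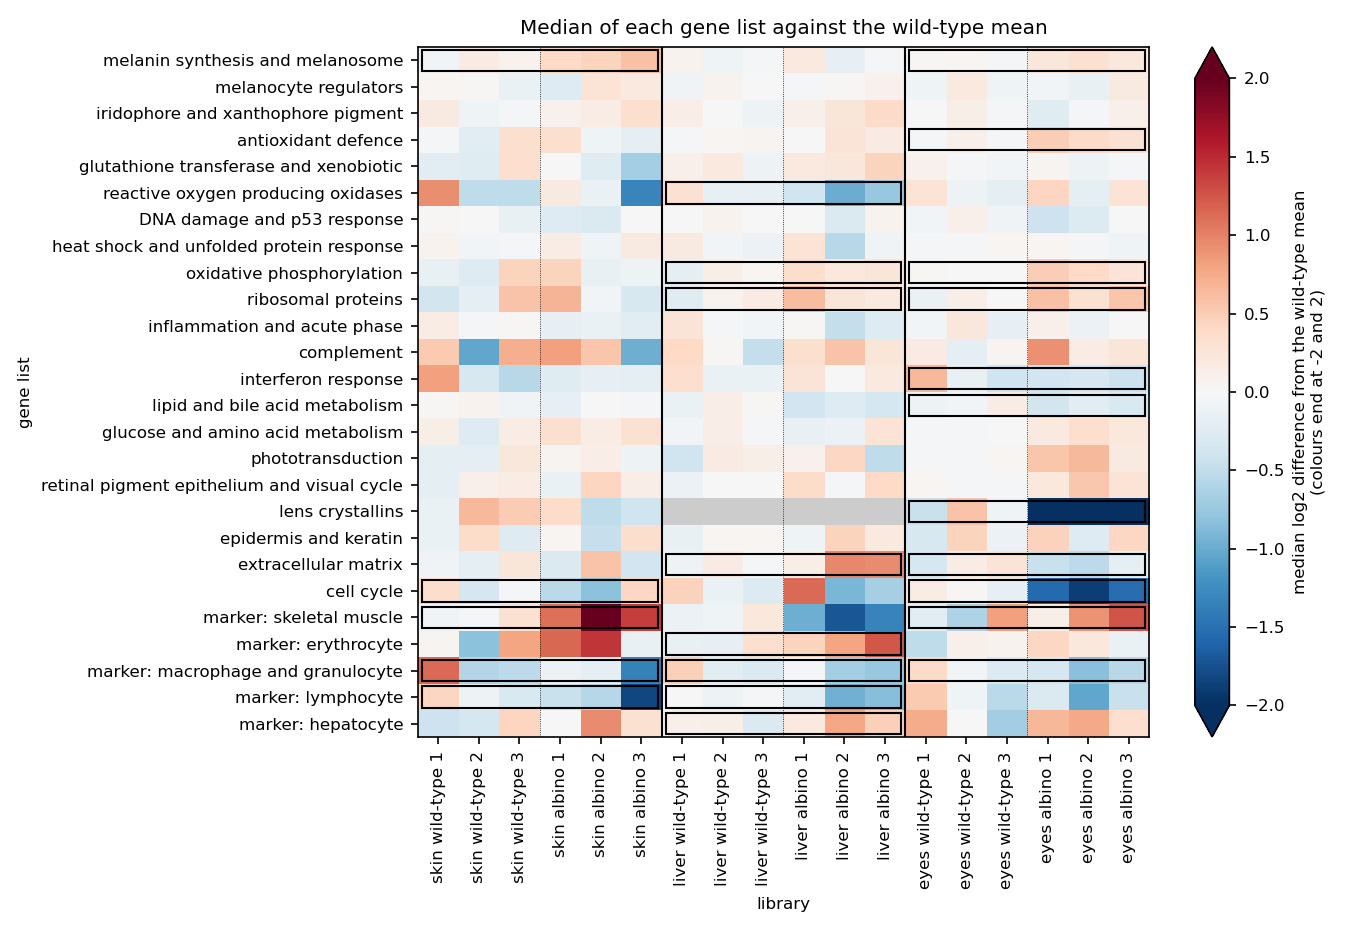
Median log2 difference from the wild-type mean of each gene list, with lists as lines and libraries as columns, colours ending at -2 and 2. Grey marks the lens list in liver, which had no tested genes, and boxes mark lists that pass camera with a preset correlation. The skeletal muscle list in liver is coloured, though its 4 tested genes were too few for a test. In liver the median albino difference of oxidative phosphorylation is 0.25, and -0.03 when libraries are scaled by their totals.

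Eyes hold pigmented tissue beside retina and lens, and the eye comparison asks how an organ that depends on melanin differs between the genotypes. Gamma crystallins, structural proteins of the lens, took the 6 places of the naming rule for genes that fell. The CRYG3-like genes LOC141147747 and LOC141121802 went from 3286 ± 1447 and 2849 ± 1040 CPM to 0 counts in albino eyes, at least 122920-fold and 107410-fold lower. The other 4, LOC141126420, LOC141126456, LOC141147745 and LOC141121740, were at least 61015-fold, 24355-fold, 14887-fold and 14548-fold lower. Of 55 gamma crystallin genes 54 were tested, and 32 fell and 0 rose in edgeR's test. How reads were shared between these near-identical copies is not given. Over unscaled library totals, summed beta crystallins stood at 0.0478%, 0.0302% and 40.6% of the wild-type mean in albino libraries 1, 2 and 3, and summed gamma crystallins at 0.00276%, 0.00262% and 9.20%. The lens list as a whole was lower (15 of 15 negative, 1 called, median -4.21, adjusted p = 4.29e-05; adjusted p = 0.720 with an estimated correlation), with lengsin (LGSN), a protein of lens fibres, at -8.14 ± 0.73. The beaded filament gene BFSP1 stood at -7.55 ± 2.45 and the lens connexin GJA3 at -4.21 ± 1.63, and neither passed.

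**Figure D3:**
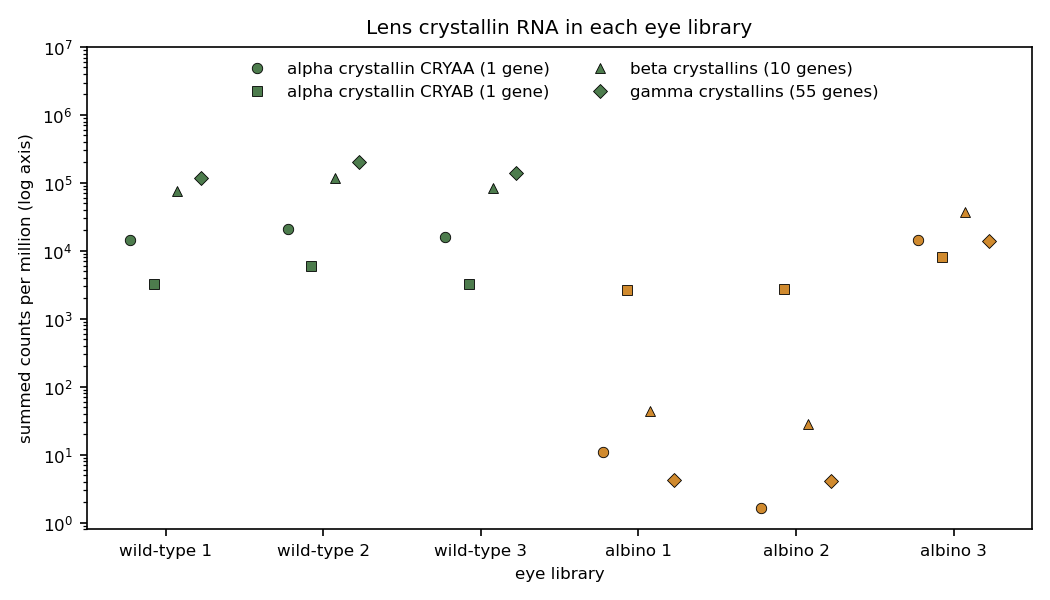
Summed CPM, over unscaled library totals, of alpha, beta and gamma crystallin genes in each eye library on a log axis, 1 point per family and library, with CRYAA and CRYAB apart. The summed gamma crystallins are 118300 to 202420 CPM in wild-type eyes and 4.23, 4.03 and 14106 CPM in albino eyes.

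Among genes that rose in albino eyes, the C3a receptor-like gene LOC141105207 had 0 counts in wild-type eyes and 3.78 ± 1.28 CPM in albino eyes, at least 123-fold more. The CXCR3-like gene LOC141110029, of a family of chemokine receptors, had 3 counts against 14.4 ± 4.98 CPM, a ratio of 469 with an interval of 160 to 2278. The olfactory receptor-like genes LOC141134329 and LOC141134328 were at least 75.1-fold and 55.8-fold higher. The beta-microseminoprotein-like gene LOC141106098 rose by 7.59 ± 1.02 and the keratin 19-like gene LOC141114312 by 6.35 ± 0.62. In all, 1995 of 17817 tested genes passed, 909 higher and 1086 lower. Groups did not overlap for 36.6% of tested genes, where chance gives 10% averaged over all splits, from which a single split can differ. Scaled by library totals, 2907 passed and 78.6% of them were higher, since that scaling moves the median of all genes to 0.28, and directions here are relative to that median. The count was 623 without wild-type 2, 825 without wild-type 3, 618 without albino 1, 458 without albino 2 and 1324 without albino 3. Without albino 1 and 2 together 62 genes passed, in a fit of 1 albino library against 3, which assumes that this library varies as the wild-type libraries do. With beta crystallin level as a covariate, which is itself lower in albino eyes, 97 passed, 29 higher and 68 lower, with 2139 at an unadjusted p under 0.05 in edgeR's test. The covariate runs close to genotype, above all in albino 1 and 2. A call lost with it can therefore reflect lost power, and does not show that lens content is the cause. Of 51 calls picked by the naming rule, 38 were lost with the covariate. The 13 that held were TOP2A, IRF7, SOD3, MYRFL, the C3a receptor-like, CXCR3-like, beta-microseminoprotein-like and keratin 19-like genes and 5 gamma crystallins, and lengsin (LGSN), TYRP1, GPX1, GPX3 and SLC24A5 were among those lost. With each library left out in turn 30 of the 51 held, and 6 were lost without wild-type 1 (adjusted p up to 0.0882), 17 without wild-type 2 (up to 0.125), 13 without wild-type 3 (up to 0.105), 19 without albino 1 (up to 0.101), 17 without albino 2 (up to 0.128) and 10 without albino 3 (up to 0.112).

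Several melanosome genes rose in albino eyes, and the transcription factor of pigment cells fell. TYRP1 rose from 349 ± 32.1 to 564 ± 28.6 CPM (log2 difference 0.69 ± 0.13, adjusted p = 0.0183), MLANA by 0.58 ± 0.11, OCA2 by 0.68 ± 0.17 and SLC45A2 by 0.59 ± 0.14. The exchanger SLC24A5 rose by 1.03 ± 0.14, the organelle biogenesis gene HPS4 by 0.81 ± 0.13 and GPR143, a receptor of the melanosome membrane, by 0.81 ± 0.13. TYR stood at 0.20 ± 0.18 (adjusted p = 0.502), PMEL at 0.31 ± 0.16 (0.252) and DCT at -0.04 ± 0.12 (0.853), and did not pass. That factor, MITF, fell by 0.96 on the log2 scale (SE 0.22) and MC1R from 1.56 ± 0.380 to 0.418 ± 0.160 CPM, while SOX10 stood at -0.46 ± 0.22. In the melanin list 8 of 28 tested genes rose and 1 fell, and 8 rose and 2 fell when adjusted over the list alone (median 0.20, adjusted p = 0.0496; adjusted p = 0.720 with an estimated correlation). That call was lost without wild-type 1 (0.0848), wild-type 2 (0.0662), wild-type 3 (0.131), albino 2 (0.0947) or albino 3 (0.0752). OCA2 (up to 0.128) and MC1R (up to 0.125) were lost without any library of the eyes, SLC45A2 (up to 0.105) without any but wild-type 1, and MITF (up to 0.110) and TYRP1 (up to 0.0764) without wild-type 2 or 3 or albino 1 or 2. MLANA was lost without wild-type 3 or any albino library (up to 0.0706), and SLC24A5, HPS4 and GPR143 held without each library. With beta crystallin level as a covariate every called gene named in this paragraph lost its call, SLC24A5, HPS4 and GPR143 among them. Since that covariate runs close to genotype, these losses do not show that lens content explains the differences. The melanin list still passed camera with that covariate.

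Antioxidant genes lay higher as a list in albino eyes, where 11 of 43 tested members rose and 1 fell, and 17 rose and 3 fell when adjusted over the list alone (median 0.36, adjusted p = 0.000398; adjusted p = 0.720 with an estimated correlation). Extracellular superoxide dismutase (SOD3) rose from 222 ± 52.5 to 848 ± 58.9 CPM, the secreted peroxidase GPX3 by 1.30 ± 0.16, the SELENOW row LOC141107750 by 1.72 ± 0.25 and the cytosolic SOD1 by 0.76 ± 0.16 (adjusted p = 0.0265). GPX1, the cytosolic peroxidase, fell from 288 ± 47.1 to 135 ± 14.7 CPM (log2 difference -1.09 ± 0.15, adjusted p = 0.00733). SOD2 stood at 0.31 ± 0.14, CAT at 0.27 ± 0.10, the stress regulator NFE2L2 at 0.39 ± 0.16 and HMOX1 at -0.59 ± 0.28, and none of these 4 passed. SOD1 lost its call without any of wild-type 1, 2 and 3 and albino 1 and 2 (adjusted p up to 0.0741). Oxidative phosphorylation genes lay higher (17 of 49 tested, 32 over the list alone, 0 lower, median 0.38, adjusted p = 2.94e-09; 0.720 with an estimated correlation), with COX6B1 at 0.69 ± 0.11, SDHD at 0.72 ± 0.12 and ATP5F1D at 0.67 ± 0.11. Genes of the mitochondrial genome took 9.05%, 8.12% and 6.70% of counts in albino eyes and 3.32% to 4.89% in wild-type eyes. The lowest of the 3 albino shares is that of library 3, which kept 40.6% of the wild-type beta crystallin RNA over unscaled totals, against 0.0478% and 0.0302% in libraries 1 and 2. The mitochondrial shares are over unscaled totals too. Of these totals, summed gamma crystallins took 118300 to 202420 CPM in wild-type eyes and 4.23, 4.03 and 14106 CPM in albino eyes. Fewer crystallin counts raise the share of all other genes, so part of the mitochondrial gap reflects lens content. How large that part is was not computed. Ribosomal protein genes lay higher (24 of 77 tested, 50 over the list alone, median 0.48, adjusted p = 4.43e-07; 0.720 with an estimated correlation), with RPL22 at 0.77 ± 0.14, RPL38 at 0.73 ± 0.14 and RPL21 (LOC141112834) at 0.84 ± 0.16. SDHD was lost without albino 2 (0.0533), ATP5F1D without wild-type 2 (0.0505), RPL22 (up to 0.0684) and RPL38 (up to 0.0614) without wild-type 2 or albino 1, and LOC141112834 without wild-type 3 or albino 1 (up to 0.0647). With beta crystallin level as a covariate, SOD3 alone of the 11 called genes named here kept its call, while the antioxidant, oxidative phosphorylation and ribosomal lists still passed camera.

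Cell cycle genes fell in albino eyes: 34 of 34 tested members were negative, 22 passed over all genes and 32 when adjusted over the list alone (median -1.80, adjusted p = 1.69e-29; adjusted p = 0.301 with an estimated correlation). TOP2A, which untangles DNA before division, fell from 35.2 ± 5.00 to 4.49 ± 1.33 CPM, the spindle protein TPX2 by 2.91 on the log2 scale (SE 0.24) and the replication helicase subunit MCM5 by 2.00 (SE 0.17). The per-library medians were 0.14, 0.02 and -0.16 in wild-type and -1.56, -1.89 and -1.52 in albino eyes, so that albino 3 lay beside the others. Albino 3 kept part of its lens RNA, but not all kinds of it. Over unscaled totals it had LGSN at 3.15 CPM (252 to 864 in wild-type eyes) and BFSP1 at 10.0 CPM (202 to 714). Its median therefore cannot tell whether lens loss plays a part in the cell cycle difference. The lipid list lay lower (9 of 32 lower and 1 higher, 13 and 4 over the list alone, median -0.38, adjusted p = 0.0188; 0.720 with an estimated correlation). Squalene epoxidase (SQLE), an enzyme of sterol synthesis, fell from 61.9 ± 11.1 to 24.6 ± 1.03 CPM. Extracellular matrix genes lay lower as a list (4 of 34 lower and 1 higher, 12 and 2 over the list alone, median -0.41, adjusted p = 0.0379; 0.754 with an estimated correlation), though albino 3 lay above wild-type 1 (per-library medians -0.34, 0.15 and 0.26 in wild-type, -0.44, -0.52 and -0.18 in albino eyes), with the collagens COL6A3 at -1.10 ± 0.15, COL5A2 at -1.09 ± 0.22 and COL6A1 at -0.97 ± 0.21. The lipid list was lost without wild-type 3 (0.0503) or albino 3 (0.0752), and the matrix list without wild-type 2 (0.0730), wild-type 3 (0.304), albino 1 (0.113) or albino 2 (0.0732). COL5A2 (adjusted p up to 0.0864) and COL6A1 (up to 0.0952) were lost without wild-type 2 or 3 or albino 1 or 2. Under the beta crystallin covariate TOP2A kept its call, while TPX2, MCM5, SQLE, COL6A3, COL5A2 and COL6A1 lost theirs. The cell cycle and lipid lists still passed camera with it.

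Interferon genes lay lower as a list in albino eyes (3 of 37 lower, 3 over the list alone, median -0.73, adjusted p = 0.0310; adjusted p = 0.720 with an estimated correlation). The groups overlapped, and wild-type 1 stood apart (per-library medians 0.65, -0.15 and -0.40 in wild-type, -0.39, -0.33 and -0.43 in albino eyes). IRF7, the factor that amplifies interferon, fell from 35.8 ± 3.45 to 2.11 ± 0.692 CPM, and the viral RNA sensors ZNFX1 and IFIH1 fell by 1.00 (SE 0.21) and 1.07 (SE 0.25) on the log2 scale. Macrophage markers lay lower (2 of 16 lower and 1 higher, 4 and 1 over the list alone, median -0.59, adjusted p = 0.0457; 0.720 with an estimated correlation), with LYZ at -1.24 ± 0.29, the growth factor receptor CSF1R at -1.24 ± 0.29 and the MARCO row LOC141147284 at -2.77 ± 0.75, which did not pass. Skeletal muscle markers lay higher as a list (2 of 25 called, 19 positive, 6 over the list alone, median 0.52, adjusted p = 0.00628; 0.754 with an estimated correlation), with per-library medians of 0.12, 0.90 and 1.26 in albino and -0.21, -0.62 and 0.82 in wild-type eyes, which overlap. Parvalbumin (PVALB), a calcium buffer of fast muscle and of some neurons, rose from 24.5 ± 9.85 to 505 ± 198 CPM, fast troponin C (TNNC2) rose by 1.74 ± 0.38, and TNNI2 stood at 1.71 ± 0.44 and did not pass. Without wild-type 1 the interferon (0.514), macrophage (0.248) and muscle (0.0848) lists lost their calls. Without wild-type 2 the macrophage (0.0528) and muscle (0.0568) lists did, without albino 2 the interferon (0.0794) and macrophage (0.147) lists, and without albino 3 all 3 (0.0752). ZNFX1 (up to 0.0944), IFIH1 (up to 0.111), LYZ (up to 0.1001) and CSF1R (up to 0.0903) were lost without wild-type 2 or any albino library, IFIH1 and CSF1R also without wild-type 1, LYZ and CSF1R also without wild-type 3, and TNNC2 (up to 0.110) without wild-type 1 or any albino library.

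Of 26 lists tested in eyes, 11 passed. With an estimated correlation camera called 0 lists, with 1 at an unadjusted p under 0.05, and fry called 5, melanin, antioxidant, oxidative phosphorylation, glucose and cell cycle. Among lists that did not pass, phototransduction had 12 members higher and 4 lower out of 32 (adjusted p = 0.147) and the visual cycle list 4 higher and 1 lower out of 18 (0.210). The glucose and amino acid list had an adjusted p of 0.0798, complement 0.111, DNA damage and lymphocyte markers 0.156, hepatocyte markers 0.246, glutathione transferases 0.408, keratin 0.458, oxidases 0.736, heat shock and erythrocyte markers 0.757, melanocyte regulators 0.837, iridophore and xanthophore genes 0.915 and inflammation 0.937. The median, the mean and the test differ in sign for the glutathione transferase and inflammation lists. With products like a member 8 lists passed, and the melanin (0.135), lipid (0.0569) and macrophage (0.0576) lists did not. With beta crystallin level as a covariate the matrix (0.564) and macrophage (0.299) lists did not.

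Which genes differ in every tissue was asked of the 13578 genes tested in all 3. Of these, 7 were called in the same direction in skin, liver and eyes, 4 higher and 3 lower. Libraries of the same number in the 3 tissues share an animal in most cases, so overlap can occur without any effect of genotype. MYRFL was higher, at 13.1 ± 0.186, 11.2 ± 0.566 and 7.13 ± 0.967 CPM in albino skin, liver and eyes, against 1, 1 and 16 counts over the wild-type libraries. FCRL5 (LOC141116641) was lower, at 2.39 ± 0.291, 3.90 ± 0.815 and 0.907 ± 0.444 CPM in wild-type animals against 1, 7 and 0 counts in albino animals, and in eyes it was at least 35.7-fold lower. The other 5, named here after their values were seen, are uncharacterized: LOC141113311, LOC141129775 and LOC141147690 were higher, and LOC141116617 and LOC141104940, which bears the symbol POL, were lower. Eyes and liver shared 74 genes higher and 58 lower, and 22 genes were called in opposite directions. Skin and liver shared 5 higher and 3 lower, and skin and eyes 4 and 5. The count of 7 was 11 without skin wild-type 3, 2 without skin albino 1 and 0 without skin albino 2 or 3, where edgeR called 0 genes in skin.

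Whether the albino difference depends on the tissue was tested by the interaction of genotype and tissue. The difference in TYR was 2.60 ± 0.35 larger in skin than in eyes (adjusted p = 0.0123) and that in PMEL 2.26 ± 0.36 larger (adjusted p = 0.0220). Other pigment genes did not pass, among them OCA2 (2.41 ± 0.57, adjusted p = 0.0786), TYRP1 (1.02 ± 0.28, 0.122) and DCT (-0.94 ± 0.46, 0.412), and the melanosome list was not tested for interaction. PLAAT1, a phospholipase of lens and other tissues, differed by 6.78 ± 0.64 (skin 0.47, eyes -6.30), the CXCR3-like gene LOC141110029 by -8.28 ± 0.80, where wild-type eyes had 3 counts, and the VWA5A-like gene LOC141121706 by -2.38 ± 0.25 (skin -0.71, eyes 1.67). Between skin and eyes 193 of 19477 genes passed, 147 with the more positive difference in skin, in a fit that treats libraries of the same number as separate animals. This balance depended on the libraries used. Without skin wild-type 1, 88 were more positive in skin and 86 more negative, and without eyes albino 1 it was 9 and 9. Without eyes wild-type 1 it was 153 and 34. With a replicate block for each genotype and number 239 passed, 145 of them among the 193. The count was 121 and 84 without skin albino 2 and 3, 19 and 32 without eyes wild-type 2 and 3, and 18 and 19 without eyes albino 1 and 2. Without eyes albino 1 and 2 together edgeR called 0, with 1265 at an unadjusted p under 0.05, and DESeq2 called 941 with all libraries.

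Between skin and liver the interaction rule picked LRAT, INHBA and PRRT3. LRAT, which esterifies retinol for storage, rose in liver by 5.18 ± 0.32 and stood at 0.35 ± 0.43 in skin, an interaction of -4.85 ± 0.49 (adjusted p = 0.00339). INHBA, which encodes the activin A subunit, rose in liver by 4.02 ± 0.28 with an interaction of -4.38 ± 0.42, and PRRT3 stood at 0.21 in skin and -5.32 in liver, an interaction of 5.55 ± 0.38. Here 49 of 18153 genes passed, 20 more positive in skin and 29 more negative. Without liver wild-type 1 there were 41 more positive and 37 more negative, and without any other library the more negative ones stayed more numerous. The count was 78, 10 and 15 without liver wild-type 1, 2 and 3, 25 and 16 without liver albino 2 and 3, and 32 and 15 without skin albino 2 and 3. With liver wild-type 2 and 3 summed it was 15, and with the replicate block 39, 28 of them among the 49.

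Between eyes and liver the interaction rule picked ACTN3, CSRP2 and PRRT3. ACTN3 stood at 0.87 ± 0.33 in eyes and at 3 counts in albino liver, an interaction of 9.86 ± 0.56 (adjusted p = 1.41e-05). CSRP2, a protein of smooth muscle and other cells, rose in eyes by 0.51 ± 0.12 and fell in liver from 3.88 ± 0.316 to 0.584 ± 0.0492 CPM, an interaction of 3.20 ± 0.21. PRRT3 stood at -0.37 ± 0.17 in eyes and fell in liver, an interaction of 4.94 ± 0.36. The collagens COL6A3, COL5A2 and COL6A1 differed by -1.96 ± 0.34, -1.73 ± 0.34 and -2.11 ± 0.38. Here 654 of 19128 genes passed, 251 more positive in eyes and 403 more negative. The count was 270 and 332 without liver wild-type 2 and 3, 411 without liver albino 3, 346 and 329 without eyes wild-type 2 and 3, and 283 and 317 without eyes albino 1 and 2. With liver wild-type 2 and 3 summed it was 334, without eyes albino 1 and 2 together 75, and with the replicate block 497, 405 of them among the 654. The block takes liver wild-type 3 as the animal of its label. The 9 calls named by the interaction rule held without each library and with the block. Without eyes albino 1 and 2 together, 3 of the 9 were lost. These were PLAAT1, difference of effects, skin vs eyes, at 7.15 (adjusted p = 0.146), LOC141110029 (CXCR3), difference of effects, skin vs eyes, at -8.17 (0.0674) and LOC141121706 (VWA5A), difference of effects, skin vs eyes, at -2.53 (0.146). That fit has 1 albino eye library, assumed to vary as the other groups do, and these differences stayed near 6.78, -8.28 and -2.38 with fewer samples.

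**Figure D4:**
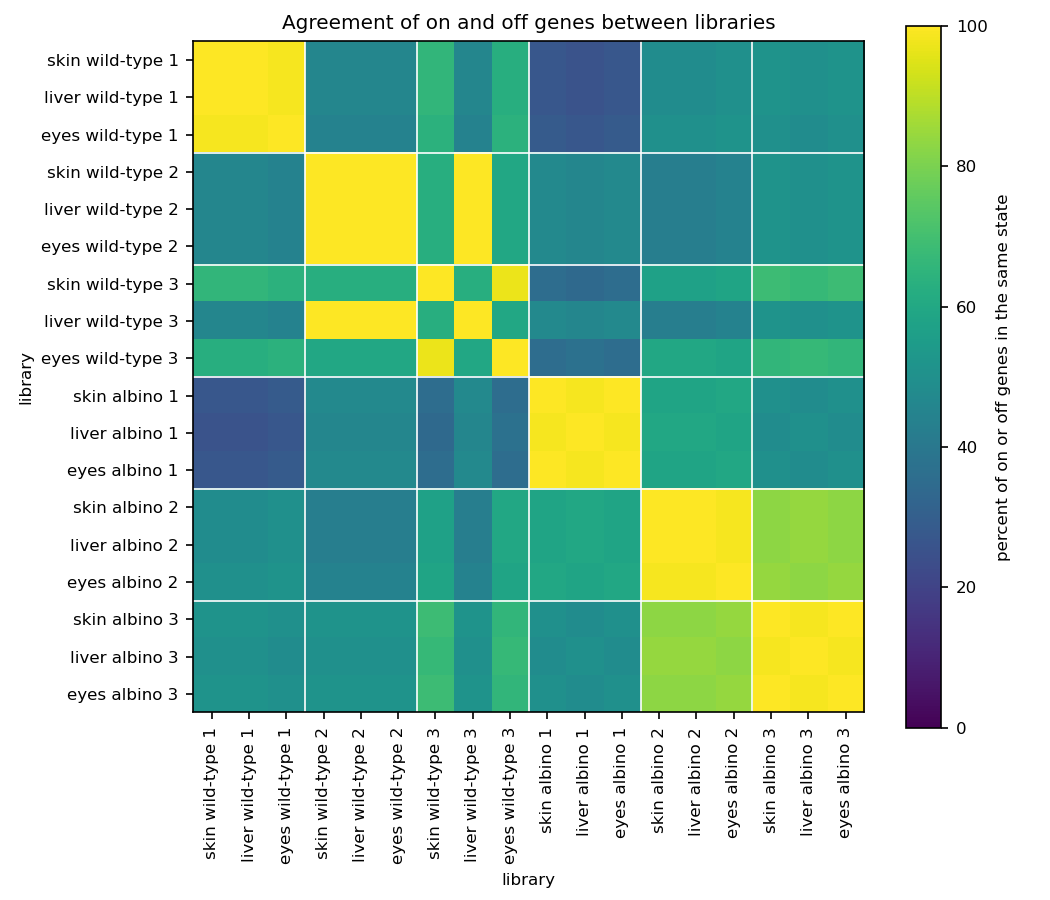
Percent of 70 genes, each on in some animals and off in others in every tissue, that have the same state in a pair of libraries, with libraries on both axes. Liver wild-type 3 has 100% in common with wild-type 2 of skin and eyes and 60% to 62.9% with wild-type 3.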

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

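The tests of lens content, crystallin copies, pigment cells, eye tissue in skin and animal identity were chosen only after the results were seen, as were the alternatives without eyes albino 1 and 2 and with a beta crystallin covariate, while the counts of other splits were not.

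Several named genes had an albino difference that was not the same in 2 tissues by edgeR's test of the interaction, with adjusted p from 1.41e-05 (ACTN3) to 0.0498 (CCDC148), and each value below is the first tissue minus the second. Between skin and eyes, TYR differed by 2.60 and PMEL by 2.26, TOP2A by 2.79, TPX2 by 2.98, the interferon factor IRF7 by 3.01, lengsin (LGSN) by 9.25 and PLAAT1 by 6.78. CCDC148 differed by 2.54, MYRFL by 4.62, the SELENOW gene LOC141107750 by -2.58, the CXCR3-like gene LOC141110029 by -8.28 and the VWA5A-like gene LOC141121706 by -2.38.

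Between skin and liver, the retinol enzyme LRAT differed by -4.85, INHBA by -4.38, PRRT3 by 5.55 and CSRP2 by 2.57. DNAH10 differed by -10.90 and the keratin 19-like gene LOC141114312 by -6.16.

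Between eyes and liver, COL6A3 differed by -1.96, COL5A2 by -1.73, COL6A1 by -2.11, LOX by -2.22, TOP2A by -2.83, TPX2 by -2.60 and RRM2 by -2.37. The peroxidase GPX1 differed by -1.95, the pigment cell factor MITF by -1.26, IRF7 by -4.13, spectrin beta (SPTB) by -1.91 and the sialyltransferase ST8SIA1 by -5.85. LRAT stood at -4.59, INHBA at -5.29, PLAAT1 at -6.87, CCDC148 at -3.18 and MYRFL at -4.77. ACTN3 differed by 9.86, CSRP2 by 3.20, PRRT3 by 4.94, TPD52L1 by 7.21, the C3a receptor-like gene LOC141105207 by 7.49, the MSMB-like gene LOC141106098 by 7.02, LOC141110029 by 8.66 and the gamma crystallin LOC141147747 by -22.81. Values of genes with 0 to 3 counts in a group, namely DNAH10, MYRFL, ACTN3, TPD52L1, LOC141114312, LOC141110029, LOC141105207 and LOC141147747, depend on the prior count and are no bounds.

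The lens list was lower in albino eyes. In libraries 1 and 2 the median lens gene stood at most at 0.0146% of its wild-type mean (percentages here are over unscaled library totals), so less lens tissue in these libraries is a candidate explanation. In library 3 the ratio of gamma to beta crystallins was 0.373, against 1.55 to 1.71 in wild-type eyes, which argued against an even loss of lens as the whole cause there. The ratio cannot judge loss of only a part of the lens. Over unscaled totals, CRYAA stood at 14583 CPM in library 3 (14506 to 21241 in wild-type eyes), but LGSN at 3.15 (252 to 864). In libraries 1 and 2 the ratio was lower still (0.0950 and 0.143), so whether less lens is the whole cause in these stays open. Summed gamma crystallins stood at 9.20% of the wild-type mean in library 3, with beta crystallins at 40.6%, which argued against reads moved between gamma copies. Reads discarded for matching several copies, and a difference between the genotypes, stay open.

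The melanosome list was higher in albino skin by camera (adjusted p = 2.67e-07; 0.160 with an estimated correlation), and TYR was its 1 member past the threshold over all genes. More pigment cells with unchanged content would raise these genes alike, and the differences of 7 genes were more unequal than their errors allow (Q = 87.0 with 6 degrees of freedom, 95% point 12.6), which argued against this as the whole cause. Genes also expressed in other cells would rise less. Eye tissue carried into skin libraries was argued against by phototransduction genes, which reached at most 0.133% of the wild-type eye level in albino skin (0.136% in wild-type skin). A difference between the genotypes in how these genes are regulated may remain and is a hypothesis.

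Liver wild-type 3 had the state of wild-type 2 of skin and eyes at 100% of 70 genes that are on in some animals and off in others, against 62.9% and 60% for wild-type 3. A candidate explanation is that liver wild-type 2 and 3 came from 1 animal. The deposit of 1 library as both was argued against, since the median squared difference of their counts was 6.27 times what counting error gives. For other pairs of a group it was 9.61 to 46.5 times. No biological explanation was tested.

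For the comparisons within a tissue, 10 splits of 6 libraries are too few for a share under 0.05. The real split gave 16, 864 and 1995 genes in skin, liver and eyes, the highest other 0, 18 and 0, so that 1 of 10 splits gave as many in each tissue. For lists, 10 of 10 splits gave as many in skin (real 5, highest other 11), 2 of 10 in liver (real 8, highest other 8) and 3 of 10 in eyes (real 11, highest other 12). The number of lists called in skin thus did not exceed that of any other split. For the genes shared by all tissues 1 of 100 drawn combinations gave as many (real 7, highest other 0). Every other split called 0 genes in skin and in eyes, so draws without the real split of both could only give 0. The 1 of 100 is therefore no finer test than the 1 of 10 within a tissue. For interactions, 1 of 40 drawn splits gave as many between skin and eyes (real 193, highest other 35) and between eyes and liver (real 654, highest other 222), and 2 of 40 between skin and liver (real 49, highest other 72). These draws split the libraries of an animal apart, while libraries of the same number mostly share an animal. Only 10 splits keep animals together, too few for a share under 0.05, and between skin and eyes 1 of these gave as many (highest other 1).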

How the results depend on the processing

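Library totals, lists with products like a member, eyes without albino 1 and 2, the beta crystallin covariate and summed liver wild-type 2 and 3 were chosen only after the results were seen. Of 153 results for genes picked by the naming rule 97 were called, 26 of these passed in every setting, and none of the 97 reversed.

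Numbers of called genes depended on the tool, and the cause was not tested. DESeq2 called 757 genes in skin, 1853 in liver and 3504 in eyes, 91 in all 3 tissues, and 381, 941 and 1677 interactions for skin and liver, skin and eyes, and eyes and liver. No count filter gave 45 genes in skin and 11 in all tissues. The fit of all 18 libraries gave 680 in skin, 764 in eyes and 44 in all tissues. limma on log2 FPKM gave 80 and 113 in skin with 1 and 0.1 added, and a log2 difference of at least 1 gave 911 in eyes. With the replicate block, which pairs libraries by number, skin had 27 genes, liver 791 and eyes 937, and 19 of the 97 named calls were lost.

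The fits that drop libraries have fewer samples. Without eyes albino 1 and 2, with 1 albino library assumed to vary as the other groups do, edgeR called 62 genes in eyes, 2 in all tissues, 75 between eyes and liver and 0 between skin and eyes (1265 at an unadjusted p under 0.05; DESeq2 with all libraries 941). The beta crystallin covariate left 97 genes in eyes and 13 of 51 named calls. Summed liver wild-type 2 and 3 gave 147 genes in liver, each among the 864, 15 between skin and liver and 334 between eyes and liver. The estimated correlation left 0 lists in skin, 0 in liver and 0 in eyes by camera (1, 0 and 1 at an unadjusted p under 0.05), where fry gave 1, 1 and 5, and products like a member gave 8 lists in skin, 11 in liver and 8 in eyes, where 5, 8 and 11 had passed.

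Leaving out each library in turn gave 0 (without albino 2 or 3) to 51 (without wild-type 1) genes in skin, with 1531 and 1598 at an unadjusted p under 0.05 at the counts of 0. It gave 134 (without wild-type 2) to 1381 (without wild-type 1) in liver and 458 (without albino 2) to 1634 (without wild-type 1) in eyes. Lists ran from 2 to 9 in skin, 8 to 10 in liver and 7 to 12 in eyes, and genes in all tissues from 0 to 11. Interactions ran from 10 to 78 between skin and liver, 18 to 201 between skin and eyes and 270 to 887 between eyes and liver.

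Genes that did not pass changed sign near 0. For MITF in liver, limma with 1 added, limma with 0.1 added and library totals gave -0.00190, -0.0124 and -0.00424, for SOD1 in liver -0.0137, -0.0137 and -0.0170, and for CAT (LOC141111968 (CAT) in liver) -0.240, -0.240 and -0.241. DCT in eyes stood at 0.00340 with all 18 libraries, 0.235 and 0.237 with limma, 0.219 with library totals, 0.0217 without albino 1 and 2 and 0.0255 with the covariate.

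Leaving out each library gave ranges across 0 for genes that did not pass. In skin these were -0.00251 (without wild-type 3) to 0.638 for MITF in skin, -0.10 (without albino 1; -0.04 without wild-type 2) to 0.252 for LOC141145813 (SOD2) in skin, -0.14 (without wild-type 1; -0.01 without albino 2) to 0.414 for GPX1 in skin, and -0.188 to 0.18 (without wild-type 3; 0.07 and 0.06 without albino 2 and 3) for NFE2L2 in skin. In liver LOC141145813 (SOD2) in liver ran from -0.490 to 0.0349 (without albino 3) and LOC141111968 (CAT) in liver from -0.0752 (without albino 2; -0.04 without wild-type 3) to 0.134. In eyes DCT in eyes ran from -0.113 to 0.0125 (without albino 1).

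On simulated data 39.2% of genes changed by 2 log2 units were recovered in skin, 79.2% in liver and 78.6% in eyes at depths of 34.3 to 39.2 M counts, so genes missing from the calls are not shown to be equal.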

Other observations

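The pathway tests, the tests of neighbouring genes and the test of on and off genes were chosen only after the results were seen.

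Photoreceptor genes were among the pathways enriched in genes higher in albino eyes, with 10 of 28 phototransduction genes called, 1.82 expected, among them the receptor kinase gene GRK1 and the channel gene CNGB1. The phototransduction list had 12 members higher and 4 lower out of 32 and did not pass camera (adjusted p = 0.147), and albino eyes 1 and 2 held almost no lens RNA (beta crystallins at 0.0478% and 0.0302% of the wild-type mean over unscaled totals). Oxidative phosphorylation had 38 of 126 (8.20 expected), the ribosome 44 of 180 (11.7), pyruvate metabolism 11 of 48 (3.12), of which 8 others were lower (3.05, adjusted p = 0.252), and cardiac muscle contraction, whose called genes are mostly of the respiratory chain, 15 of 80 (5.20). Among genes lower in albino eyes were cell cycle genes, 31 of 146 (9.27 expected), DNA replication genes such as MCM5 and PCNA, 9 of 41 (2.60), and sterol synthesis genes such as SQLE, LSS and CYP51A1, 6 of 19 (1.21). In albino liver, matrix receptor genes such as COL6A1 and LAMA1 were enriched among higher genes, 9 of 65 (2.01 expected). So were cytoskeleton genes of muscle cells, 17 of 149 (4.61), whose called genes include COL6A1, LAMA1 and other matrix genes. Of 4 tested skeletal muscle markers in liver, 1 was called higher and 2 lower. Glycine, serine and threonine metabolism with PHGDH and ALAS2 was enriched among higher genes too, 7 of 39 (1.21). Genes lower in albino liver were enriched for unsaturated fatty acid synthesis, 6 of 29 (0.954 expected), glycerophospholipid metabolism, 10 of 89 (2.93), and PPAR signalling with PPARG and LPL, 8 of 62 (2.04). These 14 of 664 tests passed an exact test that samples genes, which are not independent replicates.

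Genes with large differences lay beside another such gene with another symbol and product more often than random genes in liver (8 of 128, random median 2, permutation adjusted p = 0.024) and eyes (20 of 193, random median 4, permutation adjusted p = 3e-04). The unadjusted permutation p in eyes was 1e-04, the smallest that 10000 draws can give. In skin 0 of 13 did (permutation p = 1). The order of genes is that of assembly ASM4218655v1. Pairs were left out only where the symbol or product was the same, so neighbouring members of a gene family under other names may remain in these counts. The counts cannot tell such families from shared segments of the genome that differ between the animals. Such segments are a candidate explanation, were not tested and remain a hypothesis.

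Of 141 genes on in some animals and off in others in skin and eyes, 128 had the same state in libraries of the same number. Of these, 12 split the animals by genotype, 8 on and 4 off in the albino animals, where the highest other split had 3, and 10 splits are too few for a share under 0.05.

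The gene CRYAB, a small heat shock protein also made outside the lens, stood at 2334, 2496 and 7579 CPM in albino eyes and 3232, 7548 and 3472 CPM in wild-type eyes (log2 difference -0.20, adjusted p = 0.845), while CRYAA stood at 9.60, 1.48 and 13723 CPM in albino eyes.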
